A study of Mus musculus with 8 samples.

How the data were processed

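Gene expression was measured in 2 kinds of mouse bone marrow progenitor, common myeloid progenitors (CMP) and granulocyte-monocyte progenitors (GMP), from 2 genotypes. Per the labels' protocols and the series text, the cells came from male mice of a mainly C576BL/6 background, the spelling of the labels, and were isolated on a flow sorter. G0 TERTER/+ mice were the normal group. G4/G5 TERTER/ER mice, late generations homozygous for a modified telomerase reverse transcriptase allele, were the telomere-dysfunctional group. Each of the 4 groups held 2 arrays from 2 pools, each of 4 age- and sex-matched mice. Each sample held between 5000 and 20000 sorted cells, and between 5 and 10 ng of total RNA was labelled. Replicates within a group were therefore pools of animals, and the p-values measure the spread between pools. Whether the same-numbered CMP and GMP pools of a genotype came from the same mice is not given in the sources used here. The fit treats the 8 arrays as independent, so shared mice would leave fewer independent units for the mean effect, the comparisons of cell types and the correlation of effects.

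Per the labels, RNA was extracted with Trizol, amplified with a 3' in vitro transcription kit, labelled with biotin and hybridised to an Affymetrix mouse whole-genome array. The deposited values were microarray intensities on a linear scale. Per the submitters' processing notes they were MAS5 probe-set signals, and per the series text the authors scaled each array to a target signal of 100. The mean of every array after trimming 2% of probe sets at each end was 100.001, which fits that target. Background settings, detection calls and probe-level values were not given in the sources used here. The deposited table held 45101 probe sets. The median signal per array ran from 14.3 to 18.5, and between 31.6% and 35.2% of probe sets reached a signal of 50.

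From the deposited intensities, log2(signal + 10) was computed, with no further normalization between arrays. Fold changes on this scale understate the change of genes with low signal. The 64 control probe sets were left out. The platform annotation gave exactly 1 gene symbol to 34945 probe sets, several to 932 and none to 9160, and 34741 of the single-symbol probe sets had a gene identifier in the reference gene table (assembly GRCm38.p6), which changed 0 symbols. A gene was tested where a single-symbol probe set reached a signal of 50 on at least 2 arrays, and the probe set with the highest mean signal stood for the gene. This left 8886 of 18193 genes. The files name no genome build, so no coordinates are given, and the reference table served only for names and for which genes neighbour each other.

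Genes were tested with limma 3.58.1 in R 4.3.3. One mean per group was fitted over all 8 arrays, which left 4 residual degrees of freedom and 1 shared estimate of spread. Empirical Bayes moderation used an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The 6 comparisons were G4/G5 against G0 in CMP, the same in GMP, the mean of both, the difference between both (interaction), and GMP against CMP within G0 and within G4/G5. Every adjusted p is from limma unless another tool is named. Tables and figures were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

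Gene lists were tested with limma's camera and a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison. The 29 lists were SR splicing factors, core spliceosome, hnRNP and RNA-binding regulators, p53 target genes, ATM and ATR checkpoint, homologous recombination and Fanconi, telomere maintenance, DNA replication, mitosis, oxidative phosphorylation, mitochondrial biogenesis and antioxidant, cytosolic ribosomal proteins, interferon response, inflammatory and NF-kB response, immediate early and heat shock, hematopoietic stem and multipotent, erythroid, megakaryocyte, granulocyte and monocyte progenitor, maturing neutrophil, macrophage and dendritic, eosinophil, basophil and mast cell, B lymphoid, T and NK lymphoid, stromal and endothelial, Y-linked and Xist, apoptosis regulators, senescence and cell cycle inhibitors, and Polycomb, DNA methylation and MDS-mutated regulators. Lists with under 5 members past the signal filter were not tested: T and NK lymphoid had 4 and Y-linked and Xist had 3, so 27 lists were tested. With the correlation between genes estimated from the residuals, 0 of the list calls held in any of the 6 comparisons. The fry rotation test, which asks whether a list's genes move one way on balance and compares them with no other genes, called 0, 0, 0, 0, 9 and 5 lists in the order of the comparisons above.

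The groups, tests, lists and alternatives were fixed before the data were examined, as was the rule for named genes. The rule took, per comparison, the 8 largest rises and the 8 largest falls among passing genes whose groups did not overlap and whose higher group had a mean signal of at least 100. Where fewer than 8 passed in a direction, the genes of smallest p under the same conditions filled the places. The rule added up to 4 members of each called list and 22 anchor genes. It covered 467 entries of a gene in a comparison. The text names 169 of them, chosen after their values were seen, and 11 entries outside the rule, which were S100a8, Ngp, Camp and Lcn2 and heat shock or immediate early genes.

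The series text lists the same-numbered G0 and G4/G5 pools of a cell type as paired, so the numbers were taken to pair the samples. Deviations of same-numbered pools from their group means correlated at 0.247 in CMP and 0.139 in GMP. Across cell types the correlation was 0.217 in G0 and 0.0343 in G4/G5. The fit without the pairing stayed the main one, because the series text names no test, and the pool as a block was an alternative within cell type (2 residual degrees of freedom) and shared by both cell types (3).

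Results were also computed with a pseudocount of 1 or 32, no signal filter or one of 100, quantile normalization, median centring, no intensity trend, the mean of a gene's probe sets, leaving out probe sets that can match several genes (those ending in _x_at or _s_at), only the 4 arrays compared, and leaving out each array in turn. Where an array was left out, the lone array of a group was assumed to vary like the other groups. A fit with each array's mean log2 signal of the maturing neutrophil list as a covariate was chosen after seeing the data.

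The tests were checked on simulated arrays over 8886 genes, with 100 genes changed by a log2 fold of 1 and 100 by a log2 fold of 2. At a log2 fold of 1 the 6 comparisons, in the order above, recovered 70, 73, 95, 35, 78 and 71 of 100. At 2 they recovered 100, 98, 100, 91, 99 and 99 of 100, and called between 8 and 14 unchanged genes. A simulated list shifted by 0.5 was called in all 6 comparisons, with 0 other lists. On the real arrays, with correlated genes and unequal spread, this may differ.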

Results

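The data were 8 arrays of sorted mouse bone marrow progenitors, 2 pools of 4 mice in each of 4 groups: CMP, the early progenitor of all myeloid lineages, and GMP, its descendant committed to granulocytes and monocytes, each from normal G0 mice and from telomere-dysfunctional G4/G5 mice. The comparisons ask which transcripts differ between the genotypes in each progenitor. Tert, the catalytic subunit of telomerase and the modified gene, had 2 probe sets. Their highest signals on any array were 14.9 and 9.99, below the filter of 50. The first read 8.37 and 14.5 in G0 CMP, 13.7 and 14.9 in G4/G5 CMP, 8.90 and 9.03 in G0 GMP and 13.0 and 6.69 in G4/G5 GMP. The second read 9.99 and 8.80, 0.802 and 0.753, 7.39 and 0.723, and 0.481 and 0.349 in the same groups. The allele is a fusion with the estrogen receptor, not a deletion, so Tert signal did not check the genotype labels. Xist, transcribed in female cells, reached at most 15.3, and the Y-linked gene Eif2s3y read between 323.7 and 706.6 on all arrays, which were labelled male. Ppargc1a, a regulator of mitochondrial biogenesis, was below the filter on all of its probe sets.

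The 1st principal component held 54.5% of the variance over the genes tested and parted CMP from GMP arrays. G4/G5 CMP pool 1 stood apart, at -3.6 where the other CMP arrays lay between -37.8 and -30.7. Neutrophil granule genes read far higher on that array than on G4/G5 CMP pool 2. S100a8, a calcium-binding protein of neutrophils, read 16780 and 44.3, Ngp, a neutrophil granule protein, 8262 and 20.5, Camp, an antimicrobial granule peptide, 5902 and 1.28, and Lcn2 4147 and 11.8. The median gene differed between the pools of a group by a log2 value of 0.25 in G0 CMP, 0.27 in G4/G5 CMP, 0.15 in G0 GMP and 0.13 in G4/G5 GMP.

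**Figure D1:**
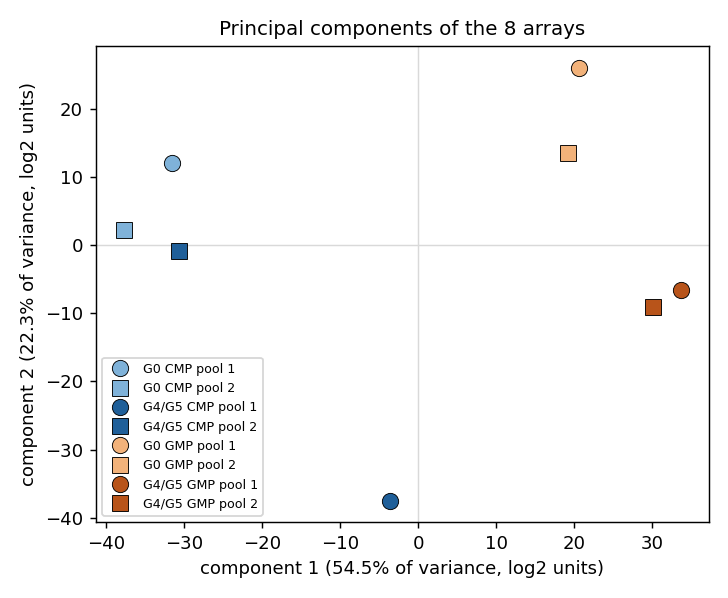
The 8 arrays on the first principal components of log2(signal + 10), in log2 units (component 1, 54.5% of the variance; component 2, 22.3%), coloured by group, circles for pool 1 and squares for pool 2. G4/G5 CMP pool 1 lies at -3.6 and -37.5, away from the other CMP arrays.

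In CMP, Taf15, an RNA-binding protein of the FET family, fell by 2.24 ± 0.20 (SE) on the log2 scale in G4/G5. It read 380 and 322.7 in the G0 pools and 65.3 and 67.1 in the G4/G5 pools (limma, adjusted p = 0.0208). No other of the 8886 genes passed: 0 were higher and 1 was lower, while 1194 had an unadjusted p under 0.05 against 444 from chance. With the pool as a block, 2 genes passed within cell type and 3 with the block shared, among them Malat1 under both (adjusted p = 0.0291 and 0.0232) and Ly86 under the shared one (0.0442). With quantile normalization 3 were higher and 3 lower, and with median centring 2 and 3. Genes close to the threshold that did not pass were Ly86, a partner of an innate immune receptor (log2 1.66 ± 0.19, adjusted p = 0.0606), and Cuedc1 (1.95 ± 0.23, adjusted p = 0.0606). Others were the lymphocyte inhibitory receptor Btla (1.45 ± 0.19, adjusted p = 0.0777) and the lysosomal protease Ctsz (adjusted p = 0.0821). On the lower side were the nuclear noncoding RNA Malat1 (-1.26 ± 0.16, adjusted p = 0.0738, with other probe sets of the gene differing in sign), and Rhobtb3 (-1.48 ± 0.19, adjusted p = 0.0758). Lower values were also found for the ubiquitin ligase Nedd4 (adjusted p = 0.0821), Slfn8 (adjusted p = 0.0919), Mctp1 (-1.81 ± 0.28, adjusted p = 0.123), the kinesin Kif22 (-0.99 ± 0.15, adjusted p = 0.124) and the cohesin loader Nipbl (-0.89 ± 0.14, adjusted p = 0.124). Without G0 CMP pool 1 8 genes passed, without G0 CMP pool 2 112, without G4/G5 CMP pool 1 3 and without G4/G5 CMP pool 2 425 (691, 1795, 909 and 2014 at an unadjusted p under 0.05). Without G0 GMP pool 1 or 2, 0 passed by limma (910 and 907 at an unadjusted p under 0.05), and Taf15 then had adjusted p = 0.118. On the 4 CMP arrays alone 0 genes passed by limma (459 at an unadjusted p under 0.05), with adjusted p = 0.184 for Taf15.

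Genes of the granulocyte and monocyte lineage lay higher in G4/G5 CMP. In the granulocyte and monocyte progenitor list 28 of 29 members lay higher (median log2 0.93, adjusted p = 2.60e-12 by camera; adjusted p = 0.378 with an estimated correlation). Of these, 0 passed over all genes and 11 adjusted over the list alone. The median ran from 0.69 without G4/G5 CMP pool 1 to 1.28 without G0 CMP pool 2. Its members include the primary granule proteases Elane, at 72.3 and 193.6 in G0 against 535.3 and 314.8 in G4/G5 (log2 1.70 ± 0.40, adjusted p = 0.239), and Prtn3 (1.45 ± 0.28, adjusted p = 0.207). They also include myeloperoxidase, Mpo (1.17 ± 0.33, adjusted p = 0.277), the chemokine receptor Ccr2 (1.16 ± 0.26, adjusted p = 0.234) and Cst7, a cysteine protease inhibitor (0.93 ± 0.16, adjusted p = 0.146). The maturing neutrophil list had all 27 members higher (median 2.51, adjusted p = 3.04e-08; adjusted p = 0.394 with an estimated correlation), with 0 passing over all genes and 2 adjusted over the list alone. This rested on G4/G5 CMP pool 1: without it the median was 0.09 (adjusted p = 0.797), and without pool 2 it was 4.44. Ifitm6 read 3293 in pool 1 and 75.0 in pool 2, against 11.1 and 26.3 in G0. Members with less difference between the pools were Anxa3 (722 and 444.3, against 149.5 and 273 in G0, log2 1.44 ± 0.29, adjusted p = 0.225) and the oxidase subunit Ncf1 (1.23 ± 0.28, adjusted p = 0.237). Part of this list also gave signal in G0, with 4 of 27 members at 100 or more on both G0 CMP arrays and 8 on both G0 GMP arrays. Signal alone does not tell expression by the progenitors from carried-over RNA.

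**Figure D2:**
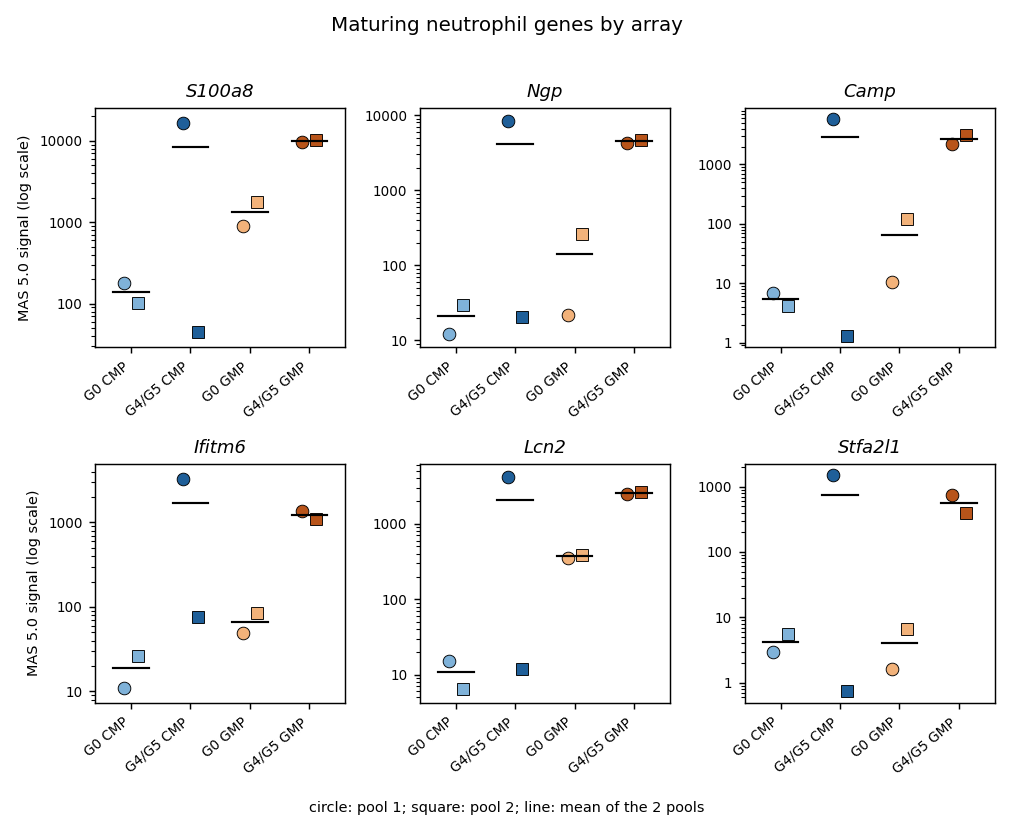
MAS5 signal of 6 maturing neutrophil genes (log axis) on each array, by group, circles for pool 1, squares for pool 2 and lines for the mean of both. S100a8 reads 16780 in G4/G5 CMP pool 1, 44.3 in pool 2, and 9762 and 10310 in the G4/G5 GMP pools.

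Markers of eosinophils, basophils and mast cells and of macrophages rested in part on the same array. The eosinophil, basophil and mast cell list had all 12 members higher in G4/G5 CMP (median 0.94, adjusted p = 5.96e-07; adjusted p = 0.378 with an estimated correlation), with 0 passing over all genes and 6 adjusted over the list alone. Its median was 0.39 without G4/G5 CMP pool 1. Prg2, the eosinophil major basic protein, read 2951 in pool 1 and 230.1 in pool 2, against 107.8 and 34.8 in G0. Fcer1g, an Fc receptor chain, had log2 1.66 ± 0.41 and the basophil protease Mcpt8 0.73 ± 0.19, and neither passed. The macrophage and dendritic list had all 13 members higher (median 0.88, adjusted p = 4.80e-05; adjusted p = 0.378 with an estimated correlation), 0 passing over all genes and 3 adjusted over the list alone, and without G4/G5 CMP pool 1 its median was 0.41 and its adjusted p = 0.0976, and without pool 2 the median was 1.41. The lysosomal glycoprotein Cd68 in it had log2 1.19 ± 0.28. The inflammatory and NF-kB list had 17 of 20 members higher (median 0.28, adjusted p = 0.0154; adjusted p = 0.378 with an estimated correlation), 0 passing over all genes and 2 adjusted over the list alone, with Cebpd, a granulocytic transcription factor, at log2 1.58 ± 0.34 (adjusted p = 0.234). Its median was 0.16 without G4/G5 CMP pool 2. That call was lost without G0 CMP pool 1 (adjusted p = 0.111, median 0.08) and without G4/G5 CMP pool 1 (adjusted p = 0.0985), although its median was 0.32 without the latter. It was also lost with no signal filter (adjusted p = 0.0730).

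Transcripts of protein synthesis and respiration lay higher in G4/G5 CMP. The cytosolic ribosomal protein list had 40 of 43 members higher (median 0.44, adjusted p = 1.49e-14; adjusted p = 0.394 with an estimated correlation). Over all genes 0 passed, while adjusted over the list alone 34 were higher and 1 was lower. Rps19 read 6635 and 8271 in G0 and 9994 and 11430 in G4/G5 (log2 0.53 ± 0.13), and Rplp0 had log2 0.57 ± 0.14. These transcripts are among the brightest on the array, and with quantile normalization the list's median was -0.01 (adjusted p = 0.348). Its median was 0.28 without G0 CMP pool 1. The oxidative phosphorylation list had 55 of 60 members higher (median 0.26, adjusted p = 8.53e-09; adjusted p = 0.394 with an estimated correlation), 0 of them passing over all genes or adjusted over the list alone. Its median was 0.14 without G4/G5 CMP pool 1. Its members include Uqcrh of complex III (0.53 ± 0.12) and Cox4i1 of complex IV (0.45 ± 0.11), which did not pass.

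Transcripts of DNA replication and repair lay lower in G4/G5 CMP. In the DNA replication list 36 of 41 members lay lower (median -0.30, adjusted p = 3.72e-08; adjusted p = 0.394 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. The median was -0.11 without G0 CMP pool 1, -0.13 without G4/G5 CMP pool 1 and -0.48 without G4/G5 CMP pool 2. Rrm1, a ribonucleotide reductase subunit, had log2 -0.44 ± 0.13 and Pola1, a polymerase alpha subunit, -0.63 ± 0.20. The ATM and ATR checkpoint list had 19 of 24 members lower (median -0.23, adjusted p = 2.52e-04; adjusted p = 0.394 with an estimated correlation), among them Nbn at -0.39 ± 0.17. In the homologous recombination and Fanconi list 18 of 25 lay lower (median -0.16, adjusted p = 0.00422; adjusted p = 0.378 with an estimated correlation), with the helicase Brip1 at -0.72 ± 0.25. In the mitosis list 29 of 49 lay lower (median -0.06, adjusted p = 0.0142; adjusted p = 0.497 with an estimated correlation), with Smc4 at -0.50 ± 0.13 and Cenpe at -0.79 ± 0.20. In these 3 lists 0 members passed, over all genes or adjusted over the list alone. When G4/G5 CMP pool 1 was left out they had adjusted p = 0.515, 0.0985 and 0.121, and without G0 CMP pool 1 the last 2 had 0.0600 and 0.251. The medians ran from -0.48 without G4/G5 CMP pool 2 to -0.04 without pool 1 for ATM and ATR, from -0.22 without G0 CMP pool 2 to -0.05 without G4/G5 CMP pool 1 for recombination, and from -0.11 without G4/G5 CMP pool 2 to -0.03 without G0 CMP pool 1 for mitosis. With the neutrophil covariate, chosen after seeing the data, the replication list kept its call (median -0.12, adjusted p = 0.00233). The other 3 lost theirs (adjusted p = 0.492, 0.121 and 0.145), with medians of -0.03, -0.05 and -0.03 and an SD over the members of 0.21, 0.29 and 0.23, against 0.17, 0.25 and 0.27 without the covariate.

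Of the splicing and RNA-binding genes in the lists, Taf15 alone passed in CMP. The SR splicing factor list had 11 of 16 members lower (median -0.15, adjusted p = 0.0217; adjusted p = 0.490 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone. Srsf2, a splicing factor mutated in myelodysplastic syndromes, read 3351 and 2792 in G0 and 2537 and 2620 in G4/G5 (log2 -0.25 ± 0.12, adjusted p = 0.411). That probe set can match several genes, and without such probe sets the gene was read by a dim one, at 44.6 and 50.5 in G0 and 48.9 and 72.2 in G4/G5, with a log2 change of 0.28 (adjusted p = 0.650). Srsf10 had -0.54 ± 0.20. The hnRNP list had 27 of 37 members lower (median -0.06, adjusted p = 0.00166; adjusted p = 0.394 with an estimated correlation), with Taf15 the single member passing, both over all genes and adjusted over the list alone. The core spliceosome list was not called (adjusted p = 0.340; its median of 0.01 was above 0 and its mean of -0.02 below). The SR list without G4/G5 CMP pool 1 had adjusted p = 0.787 and a median of 0.05, and the hnRNP list 0.300 and a median of -0.01; without pool 2 their medians were -0.28 and -0.18. Without G0 CMP pool 1 the SR list had adjusted p = 0.251.

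Targets of p53 lay higher in CMP, with 20 of 24 members above 0 (median 0.26, adjusted p = 0.00393; adjusted p = 0.378 with an estimated correlation) and 0 passing over all genes or adjusted over the list alone. Zmat3, an RNA-binding p53 target, read 42.3 and 40.8 in G0 and 120.5 and 75.8 in G4/G5 (log2 1.04 ± 0.27), the cell cycle inhibitor Cdkn1a had 0.63 ± 0.21 and Ccng1 0.36 ± 0.14. Without G4/G5 CMP pool 1 the call was lost (adjusted p = 0.171) at an equal median of 0.26. With the neutrophil covariate it was lost as well (adjusted p = 0.159), again at a median of 0.26 (SD over the members 0.37, against 0.40 without the covariate), while the median SE of the members was 0.23 against 0.20. The immediate early and heat shock list had 18 of 23 members lower (median -0.38, adjusted p = 0.00238; adjusted p = 0.378 with an estimated correlation), 0 passing over all genes or adjusted over the list alone. G0 CMP pool 2 stood apart in it, with Egr1 at 1920, Fos at 3266 and Jun at 501.6, against 254, 66.2 and 33.2 in G0 CMP pool 1. Without G0 CMP pool 2 the list's median was 0.03 (adjusted p = 0.307), and without G4/G5 CMP pool 1 or 2 the median was -0.23 (adjusted p = 0.101) or -0.62. The hematopoietic stem and multipotent list had 18 of 27 members lower (median -0.14, adjusted p = 0.0489; adjusted p = 0.394 with an estimated correlation), with the homeobox gene Meis1 at -0.46 ± 0.16 and the receptor Tek at -0.66 ± 0.27. It was lost without G0 CMP pool 2 (adjusted p = 0.503, median -0.13), without G4/G5 CMP pool 1 (0.171, median -0.16) or pool 2 (0.0685), without either G0 GMP array (0.0601 and 0.0593), and with the pool number as a shared block (0.0548). The call was also lost with a signal filter of 100 (adjusted p = 0.339, median -0.09), without _x_at and _s_at probe sets (0.0961, median -0.08), with median centring (0.0816), with a pseudocount of 1 (0.0760) and with the neutrophil covariate (0.135). Its median was -0.22 without G0 CMP pool 1 and -0.23 without G4/G5 CMP pool 2. The Polycomb, DNA methylation and MDS-mutated regulators list had 25 of 33 members lower (median -0.21, adjusted p = 0.00166; adjusted p = 0.394 with an estimated correlation), with the cohesin subunit Rad21 at -0.48 ± 0.14 and the methyltransferase Dnmt3b at -0.51 ± 0.16. It had adjusted p = 0.168 and a median of -0.04 without G4/G5 CMP pool 1, and a median of -0.32 without pool 2. In the last 2 lists 0 members passed, over all genes or adjusted over the list alone.

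The other lists were not called in CMP, among them apoptosis regulators (median 0.18, adjusted p = 0.0983), erythroid (0.23, adjusted p = 0.340), senescence and cell cycle inhibitors (-0.13, adjusted p = 0.340), megakaryocyte (-0.12, adjusted p = 0.383), stromal and endothelial (0.38, adjusted p = 0.419). Also not called were telomere maintenance (-0.02, adjusted p = 0.491), interferon response (0.10, adjusted p = 0.491), B lymphoid (median 0.09 but mean -0.02 and a lower direction by camera, adjusted p = 0.942) and mitochondrial biogenesis and antioxidant (0.02, adjusted p = 0.963). The megakaryocyte list was called lower without G4/G5 CMP pool 1 (median -0.46, adjusted p = 6.19e-06) and higher without pool 2 (0.41, adjusted p = 0.0293). Without pool 2 the core spliceosome list was also called lower (-0.10, adjusted p = 0.0418) and the erythroid list higher (0.49, adjusted p = 0.0102). Without G0 CMP pool 1 the erythroid (0.36, adjusted p = 0.0218) and interferon lists (0.05, adjusted p = 0.0460) were called higher, and with no signal filter the erythroid list (0.26, adjusted p = 0.0287).

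**Figure D3:**
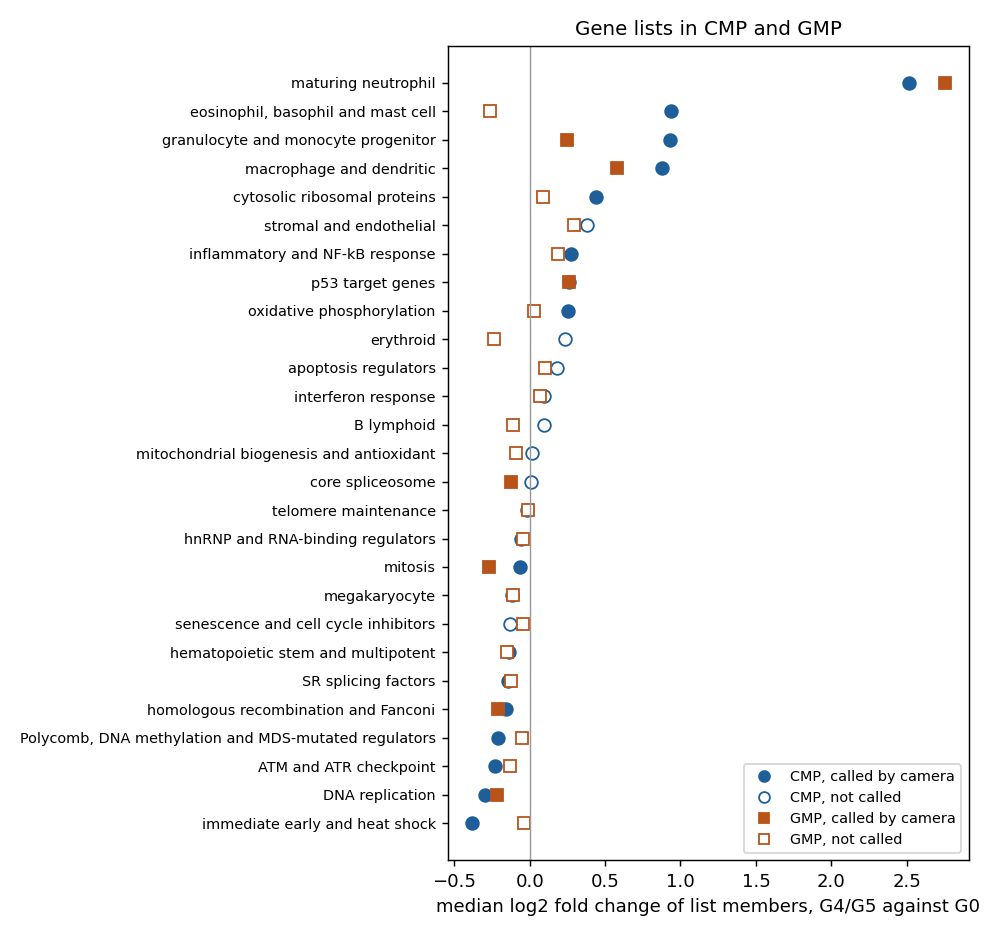
Median log2 fold change of the members of 27 gene lists in G4/G5 against G0 (x axis), circles for CMP and squares for GMP, filled where limma's camera called the list at a preset correlation. Maturing neutrophil lies farthest right, at 2.51 in CMP and 2.75 in GMP, and immediate early and heat shock farthest left in CMP, at -0.38.

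In GMP, neutrophil granule genes read higher in both G4/G5 pools. Camp read 2229 and 3107 against 10.5 and 120 in G0, Ngp 4257 and 4743 against 22.1 and 258.2, the siderophore-binding protein Lcn2 2499 and 2602 against 352.4 and 387.9, and Stfa2l1 737.9 and 389.8 against 1.60 and 6.63. S100a8 read 9762 and 10310 against 898 and 1753, Ifitm6 1369 and 1101 against 49.8 and 84.3, and the gelatinase Mmp9 195 and 228.8 against 1.09 and 26.9. The maturing neutrophil list had all 27 members higher (median 2.75, adjusted p = 5.14e-13 by camera; adjusted p = 0.631 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone. The shared estimate of spread takes in both CMP pools of G4/G5, which differ widely in these genes. On the 4 GMP arrays alone 24 of the 27 passed, with log2 2.75 ± 0.10 for Lcn2 (adjusted p = 2.00e-06) and 5.68 ± 0.64 for Camp (adjusted p = 0.00189).

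By limma over all 8 arrays 0 genes passed in GMP, with a smallest adjusted p of 0.166, while 699 had an unadjusted p under 0.05 against 444 from chance. On the 4 GMP arrays alone 360 passed, 264 higher and 96 lower, and over the arrays without G4/G5 CMP pool 1 or pool 2, 42 and 55. The count at an unadjusted p under 0.05 was 149 and 526 without G0 GMP pool 1 or 2 and 272 and 265 without G4/G5 GMP pool 1 or 2, 3 of them below the 444 from chance, and 1091 without either G4/G5 CMP pool. Taf15 had log2 -1.72 ± 0.20 (adjusted p = 0.166; 0.00137 on the GMP arrays alone) and Rhobtb3 -1.30 ± 0.19 (adjusted p = 0.482; 0.00237 alone). On the GMP arrays alone 28 of 39 named genes passed, among them on the lower side the coagulation inhibitor Tfpi (-1.17 ± 0.14), the gap junction protein Gja1 (-1.24 ± 0.19) and Bex1 (-1.63 ± 0.14). On the higher side they included Pisd-ps3 (0.77 ± 0.09), the actin regulator Eps8 (1.60 ± 0.17) and the glucose transporter Slc2a3 (0.98 ± 0.13).

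Targets of p53 lay higher in GMP in 19 of 24 members (median 0.26, adjusted p = 7.35e-04; adjusted p = 0.628 with an estimated correlation), with 0 passing over all genes, 2 adjusted over the list alone and 3 on the GMP arrays alone. Trp53inp1, a p53-induced regulator of cell death, read 100.5 and 200.3 in G0 and 382.2 and 386.8 in G4/G5 (log2 1.37 ± 0.30, adjusted p = 0.595), Zmat3 had 1.05 ± 0.27, the repair gene Ddb2 0.53 ± 0.17 and Ccng1 0.44 ± 0.14. The granulocyte and monocyte progenitor list had 26 of 29 members higher (median 0.25, adjusted p = 0.0111; adjusted p = 0.631 with an estimated correlation), 0 of them passing over all genes or adjusted over the list alone and 6 higher on the GMP arrays alone, with the heme synthesis enzyme Alas1 (0.73 ± 0.28), the repressor Gfi1 (0.49 ± 0.25) and Fcnb (1.30 ± 0.49). The macrophage and dendritic list had 11 of 13 members higher (median 0.58, adjusted p = 0.0330; adjusted p = 0.631 with an estimated correlation), 0 passing over all genes or adjusted over the list alone and 5 higher and 1 lower on the GMP arrays alone, with the lysozymes Lyz1 (1.17 ± 0.47) and Lyz2 (1.23 ± 0.54), Cd68 (0.66 ± 0.28) and the receptor Flt3 (0.98 ± 0.32). All 7 of these named genes passed on the GMP arrays alone (adjusted p between 0.00937 and 0.0440). Without G4/G5 GMP pool 2 these 2 lists had medians of 0.14 and 0.31 and were lost (adjusted p = 0.0938 and 0.164), and without G0 GMP pool 1 the macrophage list was lost (adjusted p = 0.102, median 0.52). The macrophage call was also lost with no signal filter (adjusted p = 0.539, median 0.10), without _x_at and _s_at probe sets (0.115, median 0.47) and with no intensity trend (0.0515). With the neutrophil covariate the p53 call was lost at a median of 0.20 (adjusted p = 0.101), with an SD over the members of 0.33 against 0.37 and a median SE of 0.25 against 0.20. The progenitor and macrophage calls were lost too (0.280 and 0.534), at medians of 6.46e-04 and 0.07 and an SD over the members of 0.48 and 0.67, against 0.33 and 0.65 without the covariate.

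Cell division transcripts lay lower in G4/G5 GMP. The ratios of 3' to 5' control probe sets also differed between the genotypes in GMP, at 0.822 and 0.836 in G0 against 0.881 and 0.899 in G4/G5 for Gapdh and 2.01 and 1.82 against 2.19 and 2.16 for Actb, and their part in the GMP changes was not tested. The mitosis list had 46 of 49 members lower (median -0.27, adjusted p = 7.87e-12; adjusted p = 0.628 with an estimated correlation), with the spindle motor Kif11 (-0.51 ± 0.15), the kinase Cdk1 (-0.47 ± 0.16) and Aurka (-0.50 ± 0.18). The DNA replication list had 38 of 41 lower (median -0.21, adjusted p = 2.13e-07; adjusted p = 0.631 with an estimated correlation), with the ligase Lig1 (-0.39 ± 0.11), Uhrf1 (-0.59 ± 0.19) and Pola1 (-0.52 ± 0.20). The core spliceosome list had 37 of 46 lower (median -0.12, adjusted p = 0.00192; adjusted p = 0.631 with an estimated correlation), with Luc7l (-0.45 ± 0.18), Lsm3 (-0.31 ± 0.15) and Snrpb (-0.26 ± 0.13). The homologous recombination and Fanconi list had 22 of 25 lower (median -0.21, adjusted p = 0.0107; adjusted p = 0.631 with an estimated correlation), with Rad54b (-0.52 ± 0.23) and Brip1 (-0.46 ± 0.25). In these 4 lists 0 members passed over all genes or adjusted over the list alone. On the GMP arrays alone 3 mitosis and 2 DNA replication genes were lower. Without G4/G5 GMP pool 2 the spliceosome and recombination lists were lost (adjusted p = 0.0938 and 0.137), the latter with a median of -0.10. The spliceosome median was -0.07 without G0 GMP pool 1 and -0.19 without G0 GMP pool 2. The recombination call was also lost with a signal filter of 100 (adjusted p = 0.0812). With the neutrophil covariate mitosis kept its call (median -0.20, adjusted p = 1.26e-06). Replication, spliceosome and recombination lost theirs (adjusted p = 0.303, 0.541 and 0.394), with medians of -0.12, -0.05 and -0.03 and an SD over the members of 0.21, 0.18 and 0.24, against 0.14, 0.15 and 0.18 without it. Srsf2 had log2 -0.06 ± 0.12 in GMP, and the remaining 19 lists were not called, with SR splicing factors at a median of -0.13 (adjusted p = 0.103) and cytosolic ribosomal proteins at 0.09 (adjusted p = 0.159). Of these, 6 were called without G0 GMP pool 1 (adjusted p between 0.00905 and 0.0388). They were the B lymphoid, erythroid, stem cell and megakaryocyte lists (lower) and the ribosomal and inflammatory lists (higher). The erythroid list was also called lower without G4/G5 GMP pool 2 (0.0109). With the pool as a block within cell type the ribosomal list was called higher (adjusted p = 0.00423) and the erythroid list lower (0.0271). With the mean of probe sets the ATM and ATR, SR, erythroid and immediate early lists were called lower (0.0395 to 0.0488), and with a pseudocount of 1 the erythroid list (0.0461).

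Over both cell types, 3 genes passed for the mean genotype effect, 1 higher and 2 lower, with 1582 at an unadjusted p under 0.05 against 444 from chance. Taf15 fell by 1.98 ± 0.14 on the log2 scale (limma, adjusted p = 0.00346), Rhobtb3, a Golgi-associated ATPase, fell by 1.39 ± 0.14 (adjusted p = 0.0211), and Cuedc1, a ubiquitin-binding domain protein, rose by 1.49 ± 0.16 (adjusted p = 0.0337). The direction was the same in all 4 pairs of pools for each. Rhobtb3 read 170.6, 206.9, 118.2 and 127.9 in the G0 arrays and 54.2, 68.7, 46.1 and 41.9 in G4/G5, and Cuedc1 38.8, 44.9, 20.9 and 15.1 against 196.6, 184.2, 41.1 and 53. Close to the threshold but not passing were Mctp1 (-1.52 ± 0.20, adjusted p = 0.0828) and Slfn8 (-1.34 ± 0.18, adjusted p = 0.0828). So were Tfpi (-1.06 ± 0.15, adjusted p = 0.0965), Btla (0.97 ± 0.14, adjusted p = 0.0965), Eps8 (1.32 ± 0.20), Bex1 (-1.53 ± 0.22) and the calcium-binding protein Efhd2 (-1.06 ± 0.15), the last 3 at adjusted p = 0.102. With the pool as a block within cell type 1 gene passed, and Rhobtb3 and Cuedc1 were lost (adjusted p = 0.0752 and 0.116), and with the shared block Cuedc1 had adjusted p = 0.0635. With quantile normalization 0 were higher and 2 lower, and with median centring 1 and 5. The count was 8 and 213 without G0 CMP pool 1 or 2, 17 and 668 without G4/G5 CMP pool 1 or 2, 1 and 0 without G0 GMP pool 1 or 2, and 1 and 1 without G4/G5 GMP pool 1 or 2. At an unadjusted p under 0.05 it was 745 and 1183 without the G0 GMP pools, 859 and 874 without the G4/G5 GMP pools, and between 1115 and 2355 without 1 CMP array. Cuedc1 was lost without G0 CMP pool 1 (adjusted p = 0.0544). Cuedc1 and Rhobtb3 were lost without each GMP array, at adjusted p between 0.170 and 0.323, and Taf15 was lost without G0 GMP pool 2 (adjusted p = 0.0536).

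**Figure D4:**
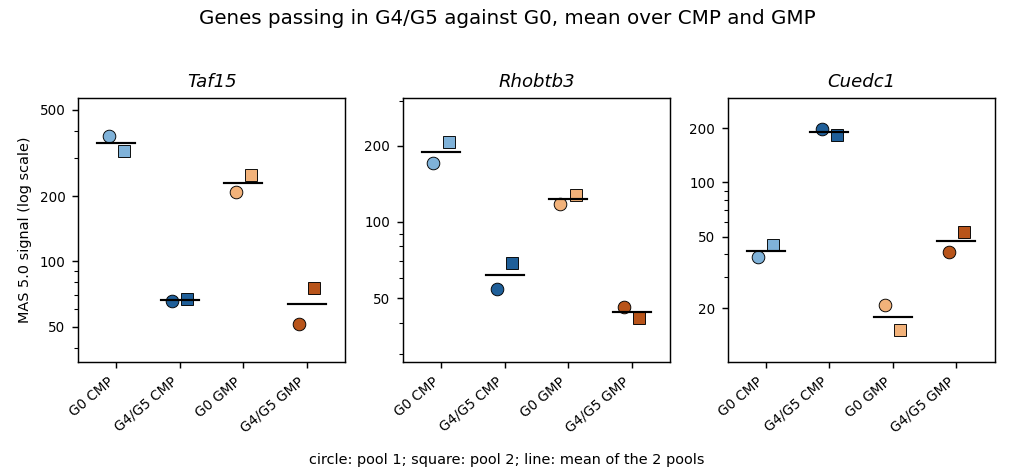
MAS5 signal of the 3 genes passing for the mean genotype effect (log axis) on each array, by group, circles for pool 1, squares for pool 2 and lines for the mean of both. Taf15 reads between 208.5 and 380 on the G0 arrays and between 51.4 and 75.2 on the G4/G5 arrays.

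Among the lists, camera called 18 for the mean, 8 higher and 10 lower, and with an estimated correlation their adjusted p lay between 0.371 and 0.461. The p53 target list had 19 of 24 members higher (median 0.27, adjusted p = 2.56e-04; adjusted p = 0.371 with an estimated correlation), with 0 passing over all genes and 8 adjusted over the list alone. Zmat3 (1.04 ± 0.19), Trp53inp1 (1.05 ± 0.21), Ccng1 (0.40 ± 0.10) and Cdkn1a (0.52 ± 0.15) did not pass over all genes, at adjusted p between 0.147 and 0.190. The DNA replication list had 39 of 41 members lower (median -0.25, adjusted p = 3.34e-10; adjusted p = 0.371 with an estimated correlation), 0 passing over all genes and 3 adjusted over the list alone, with Lig1 (-0.36 ± 0.08) and Uhrf1 (-0.57 ± 0.14). The mitosis list had 41 of 49 lower (median -0.16, adjusted p = 5.40e-08; adjusted p = 0.371 with an estimated correlation), 0 passing in either count, with Kif11 (-0.44 ± 0.11). The immediate early and heat shock list had 17 of 23 lower (median -0.16, adjusted p = 0.00290; adjusted p = 0.371 with an estimated correlation), 0 passing over all genes and 3 adjusted over the list alone, and without G0 CMP pool 2 it was lost (adjusted p = 0.189). The heat shock genes Hspa1b (-2.36 ± 0.65) and Hspa1a (-1.52 ± 0.37) were in it. The neutrophil list had a median of 2.40 (adjusted p = 7.10e-13; adjusted p = 0.371 with an estimated correlation), which was 1.15 without G4/G5 CMP pool 1 and 3.77 without pool 2, and 23 of its 27 members passed adjusted over the list alone and 0 over all genes. The granulocyte and monocyte progenitor list (median 0.62, adjusted p = 1.60e-09; 14 of 29 higher adjusted over the list alone) and macrophage and dendritic list (0.81, adjusted p = 2.78e-04; 6 of 13) had 0 members passing over all genes and adjusted p = 0.371 with an estimated correlation. Cytosolic ribosomal proteins (0.27, adjusted p = 1.60e-09; -0.00886 with quantile normalization), oxidative phosphorylation (0.16, adjusted p = 3.50e-05) and the eosinophil, basophil and mast cell list (0.38, adjusted p = 0.00873, 2 higher adjusted over the list alone) had adjusted p = 0.421 with an estimated correlation. Inflammatory and NF-kB genes (0.25, adjusted p = 0.0105) and homologous recombination (-0.17, adjusted p = 6.49e-04) had adjusted p = 0.371 with an estimated correlation. The ATM and ATR (-0.15, adjusted p = 6.49e-04), hnRNP (-0.07, adjusted p = 0.00586, with Taf15 passing in both counts), Polycomb (-0.11, adjusted p = 0.00954), SR (-0.14, adjusted p = 0.0105) and stem cell (-0.07, adjusted p = 0.0391) lists had 0.421 and core spliceosome (-0.11, adjusted p = 0.0105) had adjusted p = 0.461 with an estimated correlation.

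Single arrays moved these lists for the mean effect as well. Without G4/G5 CMP pool 1, 7 of the 18 calls were lost (adjusted p between 0.0522 and 0.212), those of the ATM and ATR, hnRNP, eosinophil, Polycomb, SR, core spliceosome and stem cell lists, with medians of -0.04, -0.03, 0.15, -0.04, -0.03, -0.06 and -0.10. When G4/G5 CMP pool 2 was left out the same lists except SR and core spliceosome had medians of -0.26, -0.13, 0.66, -0.18 and -0.09, the stem cell list was lost (adjusted p = 0.0636), and the inflammatory and immediate early medians were 0.17 and -0.32. The SR and core spliceosome lists were lost without G0 CMP pool 1, where the core spliceosome median was -0.05. There the DNA replication median was -0.16, the stem cell median -0.17 and the immediate early median -0.27. Core spliceosome was also lost without G0 GMP pool 1 (0.0624) or G4/G5 GMP pool 2 (0.0654). The stem cell list was lost without G0 CMP pool 2 (0.232), G0 GMP pool 2 (0.201) or G4/G5 GMP pool 1 (0.0674), and also with median centring (0.0587), a signal filter of 100 (0.151) or without _x_at and _s_at probe sets (0.0894). The inflammatory list was lost without G0 GMP pool 2 (0.0541). The megakaryocyte list, not called over all arrays, was called lower without G4/G5 CMP pool 1 (median -0.32, adjusted p = 1.17e-05), and the interferon list higher without G0 CMP pool 1 (0.15, adjusted p = 0.0194). With the neutrophil covariate 14 of the 18 calls were lost (adjusted p between 0.0778 and 0.995 by camera). Among them was that of the neutrophil list, by construction, since its own mean is the covariate. Ribosomal proteins, granulocyte and monocyte progenitor, DNA replication (median -0.09) and mitosis (-0.14) kept theirs, while the p53 median was 0.21 (adjusted p = 0.0778) and that of recombination -0.02 (adjusted p = 0.151). The SD over the members was 0.29 for p53 and 0.23 for recombination, against 0.33 and 0.17 without the covariate.

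The genotype effect was tested for a difference between GMP and CMP. By limma 0 genes passed, with a smallest adjusted p of 0.994 and 353 genes at an unadjusted p under 0.05, fewer than the 444 from chance. This turned on single arrays, with 499 and 725 without G0 CMP pool 1 or 2, 747 and 844 without G4/G5 CMP pool 1 or 2, and between 150 and 226 without 1 GMP array. The genes with the smallest p were Ly86, at 483.5 and 559.4 in G4/G5 GMP against 454.6 and 552 in G0 (difference of effects -1.61 ± 0.27), Ctsz (-1.07 ± 0.20), the mitotic ubiquitin-conjugating enzyme Ube2c (-0.78 ± 0.17), Malat1 (1.11 ± 0.22) and Nedd4 (1.14 ± 0.25), all at adjusted p = 0.994. The count was 3 without G0 CMP pool 1, 2 without G4/G5 CMP pool 1, 11 without G4/G5 CMP pool 2 and 0 without each other array. Over all 8 arrays camera called 6 lists, all with a lower effect in GMP, each at adjusted p = 0.840 with an estimated correlation. Cytosolic ribosomal proteins had a median difference of -0.37 (adjusted p = 7.54e-12), with -0.19 without G0 CMP pool 1, -0.24 without G4/G5 CMP pool 2 and -0.00839 with quantile normalization. The eosinophil, basophil and mast cell list had -1.12 (adjusted p = 8.96e-09, with 2 of 12 members lower adjusted over the list alone and Mcpt8 at -1.07 ± 0.27), oxidative phosphorylation -0.23 (adjusted p = 7.11e-08), and granulocyte and monocyte progenitor -0.63 (adjusted p = 2.74e-07, with Prtn3 at -1.28 ± 0.39). Mitosis had -0.15 (adjusted p = 0.00466) and erythroid -0.37 (adjusted p = 0.00812). Apart from those 2 eosinophil, basophil and mast cell members, 0 members of the 6 lists passed over all genes or adjusted over the list alone. In the absence of G4/G5 CMP pool 1 the respiration, progenitor and erythroid lists were lost (adjusted p = 0.0712, 0.0727 and 0.873, medians -0.12, -0.32 and -0.20). The progenitor and mitosis medians were -0.34 and -0.23 without G0 CMP pool 1, and the erythroid median was -0.60 without G4/G5 CMP pool 2. Without G0 CMP pool 2 the mitosis and erythroid lists were lost (0.315 and 0.374). Mitosis was also lost without G4/G5 CMP pool 2 (0.165) or G4/G5 GMP pool 2 (0.379), and erythroid without G0 GMP pool 2 (0.0677) or G4/G5 GMP pool 1 (0.0627).

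Lists not called for the difference over all arrays were called when 1 array was left out, and for 2 of them the direction turned on the G4/G5 CMP pools. The maturing neutrophil list (median difference 0.28, adjusted p = 0.515 over all arrays) was called higher in GMP without G4/G5 CMP pool 1 (2.49, adjusted p = 7.27e-28) and lower without pool 2 (-1.67, adjusted p = 8.21e-18). The megakaryocyte list was called higher without pool 1 (0.25, adjusted p = 0.0266) and lower without pool 2 (-0.49, adjusted p = 0.00106). Without G4/G5 CMP pool 2 the ATM and ATR (0.31, adjusted p = 2.35e-05), DNA replication (0.27), hnRNP (0.12), Polycomb (0.21) and SR (0.21) lists were also called higher, the last 4 at adjusted p between 0.00165 and 0.0355. The macrophage list was then called lower (-0.93, adjusted p = 7.87e-05). The core spliceosome list was called lower without G4/G5 CMP pool 1, G0 CMP pool 1, G0 GMP pool 2 or G4/G5 GMP pool 1 (adjusted p between 0.00718 and 0.0318). Macrophage genes were also called lower without G0 CMP pool 2, G0 GMP pool 1 or G4/G5 GMP pool 2 (0.00643 to 0.0131). Called higher were immediate early genes without G0 CMP pool 1 (0.23, adjusted p = 4.28e-04), and DNA replication (0.15) and hnRNP (0.10) without G0 CMP pool 2. So were ATM and ATR (0.20), hnRNP (0.07) and Polycomb (0.15) without G0 GMP pool 1, and Polycomb without G4/G5 GMP pool 1 (0.17), these 6 at adjusted p between 0.00260 and 0.0422. The macrophage list was called lower with either pool block, quantile normalization, median centring, no signal filter or without _x_at and _s_at probe sets (adjusted p between 0.0168 and 0.0425). The Polycomb list (0.0501 over all arrays) was called higher with the shared block, a pseudocount of 32, a signal filter of 100, quantile normalization, median centring, the mean of probe sets or without _x_at and _s_at probe sets (0.00651 to 0.0465). The hnRNP list was called higher with quantile normalization (8.51e-05) or the mean of probe sets (8.71e-04). Without _x_at and _s_at probe sets ATM and ATR was called higher (0.0481) and core spliceosome lower (0.0334).

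Across the 8886 genes the effects in CMP and GMP correlated at r = 0.596 (Spearman 0.435), with no array shared. CMP and GMP pools may share mice. Genes are not independent, so no p was taken. The value rested on G4/G5 CMP pool 1. CMP pair 1 alone correlated with GMP at 0.684 and pair 2 at 0.0820, and without G4/G5 CMP pool 1 r was 0.206. With genotype swapped in CMP pool 2 r was higher, 0.628, and in GMP pool 2 0.219. Without the neutrophil genes r was 0.523.

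Between the normal progenitors, 1845 genes differed, 939 higher and 906 lower in GMP than in CMP, with 3243 at an unadjusted p under 0.05 (limma). The ratio of 3' to 5' control probe sets is a sign of RNA quality or amplification. By the values above it parted the cell types for Gapdh and overlapped for Actb. Its part in the differences between cell types, in G0 or in G4/G5, was not tested. Granulocyte and monocyte genes were higher in GMP: Ms4a3 (log2 3.72 ± 0.66), Igsf6 (4.06 ± 0.65), the Fc receptor Fcgr3 (3.73 ± 0.77), haptoglobin, Hp (3.75 ± 0.70). Others were Elane (3.42 ± 0.40), Cst7 (1.63 ± 0.16) and Gfi1 (2.03 ± 0.25), at adjusted p between 0.00187 and 0.0147. Genes of stem, megakaryocytic and erythroid cells were lower in GMP: the thrombin receptor F2r (-3.11 ± 0.38), Slc14a1 (-3.06 ± 0.31), Aldh1a1 (-2.84 ± 0.30), and Hemgn (-2.76 ± 0.31). Lower as well were the angiopoietin Angpt1 (-2.58 ± 0.17), Meis1 (-2.11 ± 0.16), Mecom (-2.46 ± 0.31) and the erythroid factors Gata1 (-1.95 ± 0.33), Zfpm1 (-2.14 ± 0.17) and Tal1 (-1.19 ± 0.14). Egr1 (-4.97 ± 0.76) and the lymphoid enzyme Dntt (-3.57 ± 0.67) were lower too, with G0 CMP pools that differed widely, at 254 and 1920 for Egr1 and 712.7 and 149.2 for Dntt. Kit, the stem cell factor receptor, was lower (-1.02 ± 0.27, adjusted p = 0.0337), while Mpo (1.04 ± 0.33, adjusted p = 0.0561) and Cebpa, a granulocytic transcription factor (1.16 ± 0.41, adjusted p = 0.0767), did not pass. The count was 67 without G0 GMP pool 1 (1901 at an unadjusted p under 0.05) and 435 without pool 2, 1014 without G0 CMP pool 2, 1065 and 1069 without the G4/G5 GMP arrays. Of the 39 passing genes named for this comparison, 23 were lost without G0 GMP pool 1 (adjusted p between 0.0507 and 0.205), 8 without G0 GMP pool 2 (0.0524 to 0.102) and 2 without G0 CMP pool 2, Prg2 and Kit. Fcgr3 was lost without G0 CMP pool 1 (0.0540), Kit without either G4/G5 GMP array (0.0641 and 0.0642) and on the 4 G0 arrays alone (0.0525), and Mpo and Cebpa passed without G0 CMP pool 2 or either G4/G5 CMP array and with the pool number as a shared block (0.0400 and 0.0421).

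By list, 13 were called between the G0 progenitors, 7 higher and 6 lower in GMP. Oxidative phosphorylation had 58 of 60 members higher (median 0.45, adjusted p = 1.18e-14; adjusted p = 0.475 with an estimated correlation), 38 passing over all genes and 49 higher and 1 lower adjusted over the list alone, with Atp5g1 (0.96 ± 0.12) and Uqcrc1 (1.13 ± 0.16). Granulocyte and monocyte progenitor genes had 15 passing and 20 adjusted over the list alone (median 1.06, adjusted p = 5.48e-10; adjusted p = 0.475 with an estimated correlation), and the median was 1.61 without G0 CMP pool 2. The stem and multipotent list had 17 lower and 19 adjusted over the list alone (median -1.20, adjusted p = 3.12e-10; adjusted p = 0.244 with an estimated correlation). The megakaryocyte list had 9 lower and 14 adjusted over the list alone (median -1.58, adjusted p = 2.45e-08; adjusted p = 0.475 with an estimated correlation), with Plek (-2.30 ± 0.26), Mef2c (-1.77 ± 0.14) and Gp5 (-2.08 ± 0.25). The erythroid list had 7 lower and 1 higher, and 9 and 1 adjusted over the list alone (median -0.92, adjusted p = 0.00222; adjusted p = 0.475 with an estimated correlation), with the carbonic anhydrase Car2 at -1.95 ± 0.14, and its median was -0.53 without G0 CMP pool 1 and -0.61 without G0 GMP pool 1. DNA replication (median 0.37; 5 passing, 5 adjusted over the list alone), core spliceosome (0.26; 7 and 6) and mitosis (0.31; 14 and 14) were each higher at adjusted p = 2.96e-04, with Cdc45 (0.94 ± 0.15), Rrm2 (0.95 ± 0.18), Prpf31 (1.06 ± 0.19) and Aurka (1.00 ± 0.18); their adjusted p with an estimated correlation was 0.566, 0.475 and 0.475.

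The eosinophil, basophil and mast cell list was higher (median 1.17, adjusted p = 0.00367; adjusted p = 0.496 with an estimated correlation), with 5 higher and 1 lower in both counts: Prg2 (4.42 ± 0.98), Mcpt8 (1.84 ± 0.19) and the eosinophil peroxidase Epx (3.66 ± 0.65). The Polycomb list was lower (median -0.32, adjusted p = 0.00290; adjusted p = 0.475 with an estimated correlation), 13 lower and 2 higher over all genes and 14 and 2 adjusted over the list alone, with Tet1 at -1.02 ± 0.16 and Kmt2a also lower. The interferon list was lower (median -0.46, adjusted p = 0.0234; adjusted p = 0.475 with an estimated correlation), 11 lower and 1 higher, and 12 and 2 adjusted over the list alone, with Samd9l at -1.30 ± 0.17. The stromal and endothelial list was lower (median -0.94, adjusted p = 0.0282; adjusted p = 0.475 with an estimated correlation), 4 lower over all genes, and 4 lower and 1 higher adjusted over the list alone. Its members included Tek (-2.00 ± 0.27) and Pdgfrb (-1.51 ± 0.24). The neutrophil list was higher (median 1.41, adjusted p = 0.0407; adjusted p = 0.812 with an estimated correlation), with 2 higher and 1 lower in both counts, among them Anxa3 (2.78 ± 0.29). DNA replication was lost without G0 CMP pool 2 (adjusted p = 0.0556, median 0.16). The interferon list was lost without G0 CMP pool 1 (0.198). The stromal list was lost without G0 CMP pool 2 (0.0631, median -0.53) or either G4/G5 CMP array (0.0526 and 0.0543). The neutrophil list was lost without G0 CMP pool 1 (0.0898) or 2 (0.0688) or G0 GMP pool 2 (0.132, median 0.61). It was also lost with median centring (0.0567), quantile normalization (0.0524), a pseudocount of 32 (0.0666, median 0.83) or a signal filter of 100 (0.0656), and the stromal list with no signal filter (0.358, median -0.04). Called lower in addition were the ribosomal list without G0 CMP pool 1 (adjusted p = 1.65e-05, median -0.30) or G0 GMP pool 1 (0.0253), immediate early genes without G0 CMP pool 1 (0.0158, median -1.12) and the senescence list without either G4/G5 CMP array (0.0335 and 0.0345). The ribosomal list was also called lower with the shared block (0.0359) or a signal filter of 100 (0.0349), and the senescence list with that filter (0.0467). With quantile normalization hnRNP and SR were called lower (5.65e-04 and 0.0411) and recombination higher (0.0456), the last also with no signal filter (0.0404).

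In G4/G5 mice, 930 genes differed between GMP and CMP, 371 higher and 559 lower in GMP, with 2614 at an unadjusted p under 0.05 (limma). Of these, 719 were also called in G0, all in the same direction; 294 were higher in both, against 39.2 for independent lists, and 425 lower in both, against 57.0. The largest falls included Mfsd2b, a sphingolipid transporter of red cells and platelets (-3.97 ± 0.37), Slc14a1 (-3.50 ± 0.31), F2r (-3.48 ± 0.38), Aldh1a1 (-3.47 ± 0.30), the kinase-like Trib2 (-3.31 ± 0.45) and Mycn (-3.31 ± 0.19). Gata1 (-2.82 ± 0.33), Gata2 (-2.19 ± 0.18), Angpt1 (-2.70 ± 0.17) and Car2 (-2.47 ± 0.14) were lower as well. Higher values were found for Afap1 (2.81 ± 0.22), Ms4a3 (2.51 ± 0.66, adjusted p = 0.0467), Elane (2.05 ± 0.40) Anxa3 (1.69 ± 0.29) and B4galt6. Ms4a3 read 2623 in G4/G5 CMP pool 1 and 444.7 in pool 2. The count was 65 without G4/G5 GMP pool 1 and 105 without pool 2 (1323 and 1737 at an unadjusted p under 0.05), 608 without G4/G5 CMP pool 2, 1433 without G4/G5 CMP pool 1, and 390 and 394 without the G0 GMP arrays; on the 4 G4/G5 arrays alone it was 428. Of 22 genes named for this comparison 11 were lost without G4/G5 GMP pool 1 (adjusted p between 0.0623 and 0.258), 10 without G4/G5 GMP pool 2 (0.0630 to 0.178), 5 without G4/G5 CMP pool 2 (0.0503 to 0.114), and 4 without each G0 GMP array.

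Camera called 13 lists between the G4/G5 progenitors. Cytosolic ribosomal proteins were lower in GMP (median -0.51, adjusted p = 2.10e-10; adjusted p = 0.545 with an estimated correlation), 13 members over all genes and 34 adjusted over the list alone, among them Rpl7 (-0.50 ± 0.11), Rpl27a (-1.54 ± 0.21) and Rpl13a (-0.58 ± 0.14); with quantile normalization the list had a median of -0.04 (adjusted p = 0.437) and Rpl13a 0.01. In G0 this list was not called (median -0.13, adjusted p = 0.0605). The stem and multipotent (median -1.25; 13 lower, and 18 lower and 1 higher adjusted over the list alone), megakaryocyte (-1.81; 11 and 14) and erythroid (-1.17; 11 lower and 1 higher, and 12 and 1) lists were lower, at adjusted p = 3.54e-10, 1.19e-09 and 4.74e-06, and adjusted p = 0.246, 0.522 and 0.522 with an estimated correlation. Oxidative phosphorylation (0.28; 11 higher, and 15 higher and 1 lower adjusted over the list alone, with Ndufb7 at 0.78 ± 0.13), DNA replication (0.39; 3 and 2, with Cdc45 at 0.74 ± 0.15) and granulocyte and monocyte progenitor (0.59; 7 and 10) were higher at adjusted p = 4.87e-08, 7.54e-07 and 1.18e-05, each with adjusted p = 0.545 with an estimated correlation. The interferon (-0.28; 7 lower, and 9 lower and 1 higher adjusted over the list alone, with Rtp4 at -2.10 ± 0.35), stromal (-1.11; 4 and 4) and Polycomb (-0.21; 6 lower and 2 higher, and 9 and 2, with Kmt2a at -0.75 ± 0.16) lists were lower at adjusted p = 0.00689, 0.0172 and 0.0276, and adjusted p = 0.545, 0.522 and 0.545 with an estimated correlation. The neutrophil (1.44; 1 and 1), core spliceosome (0.16; 2 and 0) and mitosis (0.14; 0 and 0) lists were higher at adjusted p = 0.00130, 0.00511 and 0.0454, and adjusted p = 0.688, 0.545 and 0.688 with an estimated correlation.

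Single arrays moved several of these lists. The neutrophil median was 3.75 without G4/G5 CMP pool 1 and -0.83 without pool 2 (adjusted p = 0.00359 in the lower direction). Leaving out G4/G5 CMP pool 1, the core spliceosome, stromal and mitosis lists were lost (adjusted p = 0.224, 0.143 and 0.295; medians 0.04, -1.17 and 0.05), and the DNA replication, progenitor, megakaryocyte and Polycomb medians were 0.23, 0.93, -1.15 and -0.33. Without G4/G5 CMP pool 2 the Polycomb list was lost (0.305), and the respiration, progenitor, core spliceosome and interferon medians were 0.18, 0.35, 0.25 and -0.43. Without G4/G5 GMP pool 1 the Polycomb and mitosis lists were lost (0.0625 and 0.487). The mitosis median was 0.22 without G4/G5 GMP pool 2. Mitosis was also lost with the mean of probe sets (0.0744), no intensity trend (0.0524), quantile normalization (0.211), a signal filter of 100 (0.0909) or without _x_at and _s_at probe sets (0.205), and core spliceosome with quantile normalization (0.0814). The interferon median lay between -0.45 without G4/G5 GMP pool 2 and -0.17 without pool 1. Without G4/G5 CMP pool 2 the ATM and ATR (0.33, adjusted p = 0.00160) and recombination lists (0.28, adjusted p = 0.0253) were called higher and the p53 list lower (-0.32, adjusted p = 0.0381). Without G4/G5 GMP pool 2 the recombination list was called higher (0.27, adjusted p = 0.0326). It was also called higher with the mean of probe sets, no signal filter, quantile normalization or a signal filter of 100 (0.0148 to 0.0377), and with the last the p53 list was called lower (0.0448).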

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

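All tests of technical explanations in this part were chosen after the result was seen, except the count over other splits of the arrays.

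The genotype effect differed between GMP and CMP by the interaction test, at a preset correlation between genes, in 6 gene lists. The median log2 difference, GMP minus CMP, was -0.374 for cytosolic ribosomal proteins, -1.12 for eosinophil, basophil and mast cell genes, -0.228 for oxidative phosphorylation, -0.625 for granulocyte and monocyte progenitor genes, -0.148 for mitosis and -0.369 for erythroid genes, and none of the 6 calls held with an estimated correlation (adjusted p = 0.840 for each). Without G4/G5 CMP pool 1 the calls of oxidative phosphorylation, granulocyte and monocyte progenitor and erythroid genes were lost (adjusted p = 0.0712, 0.0727 and 0.873). Neutrophil genes were then called higher in GMP (median 2.49), and without G4/G5 CMP pool 2 lower (-1.67). Probe sets with no gene name or several took no part in the comparisons of genes; among 2099 of them, 3 passed in CMP (2 higher, 1 lower, smallest adjusted p = 0.0448 by limma) and 7 for the mean effect (4 higher, 3 lower).

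Neutrophil granule transcripts were high in G4/G5 CMP pool 1 and in both G4/G5 GMP pools, with S100a8 at 16780, 9762 and 10310. GMP RNA alone in that CMP pool, from a wrong label or sorted GMPs, would not exceed the GMP level. Yet over 21 list members the median log2 ratio of that pool to the G4/G5 GMP arrays was 0.826 (SD 0.735), with 17 above both. That pool lay 0.54 of the way from G0 CMP to G0 GMP over 937 genes higher in GMP, and 0.12 over 905 lower. Pool 2 lay at 0.2 and 0.13. GMP RNA mixed with other RNA stays open. RNA carried over from maturing neutrophils, which sorting should remove, stays open, undecided by a test. The log2 ratio of gains in the CMP pool and in GMP had an SD of 0.499 over the 21 members. A granule programme shared by the progenitors would give similar ratios, so this decides nothing. Of the list's 27 members, 8 reached 100 on both G0 GMP arrays and 4 on both G0 CMP arrays. Higher expression of these genes in G4/G5 progenitors was not tested and stays open.

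Genes that differed in all 4 G4/G5 pools could mark a segment of another strain around the modified allele, or a base difference under a probe set. Among the 100 tested genes nearest to Tert (neighbourhood from assembly GRCm38.p6), 3 belonged to the 100 genes of smallest p, Rhobtb3, Mctp1 and Mef2c, against 1.11 in random draws (permutation p = 0.1, 10000 draws), which leaves a linked segment open. Elsewhere the fullest 100-gene window held 5 (Mettl16, Gosr1, Slfn8 and Taf15 lower, Inpp5k higher) against 5.07 in random draws (permutation p = 0.76). The count ignores rank, so a small segment stays open. A base difference under single probe sets stays open, as only Cuedc1 had another past the filter. It changed by 0.676 and the one used by 1.49. Probe sets below that filter, too dim to decide, changed by -1.40, -1.10, -0.736 and 0.0422 for Rhobtb3 (highest signals 46.8, 29.3, 42.0 and 11.2) against -1.39 for the one used, by -0.694 for Taf15 against -1.98 and by 0.422 for Cuedc1. An effect of the genotype itself was not tested and stays open.

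For the mean effect over both cell types, 2 of the 34 splits of the 8 arrays that could be fitted, the real one and 1 other, passed at least as many genes as the real one, so chance is not excluded. The real split passed 3 and the highest other 43; that split set both G0 CMP pools, G4/G5 CMP pool 2 and G0 GMP pool 1 against the rest, which points to a structure of the samples. Of the 8 splits that part all 4 pairs of pools, the real one passed 3 and the highest other 0. At an unadjusted p under 0.05 the real split had 1582 genes and the highest other 1604.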

How the results depend on the processing

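The neutrophil covariate was chosen after seeing the data. Of the alternative values for named genes, 3377 kept direction and side of the threshold, 115 lost the call, 165 gained one and 11 reversed. Over the rule's 467 entries they were 8731, 332, 272 and 113, and for called lists 1354, 255, 0 and 13. With an estimated correlation 0 lists were called in any comparison, and fry called 0 in the genotype comparisons and 5 between the G4/G5 progenitors. Genes passing in CMP numbered 3 with a pseudocount of 32, 6 with quantile normalization, 5 with median centring, 3 with no intensity trend and 0 with only the CMP arrays compared. In GMP 360 passed with only the GMP arrays compared, by construction without the spread of the CMP pools. For the mean effect 1 passed with no signal filter, which tests more genes, 6 with median centring and 8 with the mean of probe sets, and between the G4/G5 progenitors 492 with no signal filter and 428 with only those arrays compared. Without _x_at and _s_at probe sets 10 lists were called for the difference and Srsf2 in CMP had log2 0.28. With quantile normalization the ribosomal median was -0.0149 in CMP, -0.00886 for the mean and -0.00839 for the difference, and Rpl13a between the G4/G5 progenitors was 0.00989. With the neutrophil covariate 2 genes passed in CMP, 1 in GMP and 1 for the difference, and 6 lists were called in CMP, 6 in GMP, 6 for the mean and 10 for the difference. It ended 12 of 17 list calls in CMP, 7 of 8 in GMP and 14 of 18 for the mean, and 0 of 6 for the difference. In GMP mitosis alone kept its call, and 5 other lists were called. Within groups the neutrophil list differed chiefly between the G4/G5 CMP pools (mean log2 signal 9.74 and 5.13), so this fit rests mostly on that pair. That covariate gave in CMP log2 -1.51 for S100a8, -0.22 for Ngp, -0.66 for Camp and a neutrophil median of 0.0892, and in GMP -1.94 for S100a8, -1.69 for Lcn2, a granulocyte and monocyte progenitor median of 6.46e-04 and a macrophage median of 0.0654. For the mean it gave medians of 0.0569 for ATM and ATR, 0.0415 for hnRNP, -0.19 for eosinophil, basophil and mast cell, 0.00774 for SR and 0.0387 for core spliceosome genes, and between the G0 progenitors -0.30 for the neutrophil list. These list directions are camera's, which a median need not share. Leaving out each array in turn gave from 0 to 425 genes in CMP, 0 to 55 in GMP, 0 to 668 for the mean, 0 to 11 for the difference, 67 to 2551 between the G0 and 65 to 1433 between the G4/G5 progenitors. Called lists then numbered 6 to 19, 5 to 13, 12 to 17, 6 to 13, 10 to 14 and 10 to 15 in the same order, and the correlation of CMP and GMP effects lay between 0.206 and 0.654. Reversed in CMP were Hspa1b without G0 CMP pool 1 (0.32, from -3.17 without pool 2), Fos without G0 CMP pool 2 (0.44, from -4.98 without pool 1), and S100a8 (-1.43) and Camp (-0.45) without G4/G5 CMP pool 1, at 6.84 and 8.59 without pool 2. Between the G4/G5 progenitors the neutrophil median was -0.83 without G4/G5 CMP pool 2 and 3.75 without pool 1. Except where stated, the cause was not tested. Signal over background limits the low genes: detection calls were not used, and Tert and Ppargc1a, below a signal of 50, have no usable level.

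With the pool within cell type as a block, 2 genes passed in CMP (Malat1 gained, adjusted p = 0.0291) and 1 for the mean, where Cuedc1 and Rhobtb3 were lost. With the pool number as a block shared by CMP and GMP, 3 passed in CMP (Malat1 and Ly86 gained), Cuedc1 was lost for the mean, the stem cell list was lost in CMP (adjusted p = 0.0548), and Cebpa and Mpo passed between the G0 progenitors. No other call of a gene or list named in the results was lost with either block. Lists gained within cell type were the ribosomal (adjusted p = 0.00423) and erythroid lists (0.0271) in GMP and the macrophage list for the difference (0.0424). Those gained with the shared block were the macrophage (0.0370) and Polycomb lists (0.0453) for the difference and the ribosomal list between the G0 progenitors (0.0359). A block within cell type says nothing of the comparisons between cell types, which were not fitted with it.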

Other observations

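Hspa1b, an inducible heat shock chaperone, read 312.7 and 18.8 in G0 CMP, 15.5 and 40.4 in G4/G5 CMP, 666 and 359 in G0 GMP and 37.0 and 45.3 in G4/G5 GMP. On the GMP arrays alone its log2 change was -3.29 (limma, adjusted p = 2.06e-04), while over all arrays it did not pass in GMP.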
